A study of Mus musculus with 12 samples.

How the data were processed

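Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on C2C12 cells, a mouse myoblast line that fuses into myotubes when serum is reduced. Per the labels' protocols, differentiation was induced in medium with horse serum that held either the LSD1 inhibitor S2101 at 10 µM or the vehicle, and cells were crosslinked with formaldehyde after 48 h, on day 2. Chromatin was fragmented by sonication and pulled down with antibodies against mono-, di- or trimethylated lysine 4 of histone H3 (H3K4me1, H3K4me2, H3K4me3) or against H3 itself, and libraries were sequenced on an Illumina NextSeq, again per the labels' protocols. The series holds 12 samples from 2 experiments. H3K4me1 and H3K4me2 come from experiment 1, and H3K4me3 and H3 from experiment 2, and each experiment has an input for each treatment. Peak lists of 6 samples were analysed here, 1 per mark and treatment. The 4 inputs and the 2 H3 samples were not analysed here. The labels call the cells of the experiment 2 input and H3 samples differentiated and those of all other samples differentiating, while the treatment protocol is the same for all.

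Each deposited file is a list of peaks with chromosome, start, end, name and score. Per the file headers, peaks were called with MACS within Galaxy, and each file belongs to a single library, so peaks were called per library. The deposited score is the authors' own value for each peak as the caller wrote it. MACS of the 1.x series writes −10 × log10 of the p-value in that column, although the headers do not name the quantity or the version. Scores run from 100 to 3233.06 over the 6 lists, and many stand at exactly 3100, with few above it. Shares of peaks at the score limit count scores of 3100 or more. Per the submitters' processing notes, Bowtie2 and deepTools were used and the build is mm9. The settings of the aligner and caller, the treatment of duplicates, the input used and the read counts are not given in the sources used here. The depth of the libraries is therefore unknown, and no value was scaled for it. A library with fewer reads, weaker enrichment or another fragment length estimate can give fewer, narrower and lower-scoring peaks, or more peaks where wide ones are split. Differences between lists can therefore come from the library as well as from the treatment. Coordinates are mm9 and 1-based, and no peak was left out here for lying in repeated sequence. The gene table at hand is of GRCm38 (77 peaks on chromosome 1 lie beyond its last gene there), so no gene names or annotation were attached, regions are given by position, and the planned counts of gene promoters and of gene lists were not made.

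All comparisons were descriptive, because each mark and treatment has 1 library: there is no replicate check and no p-value between treatments. A peak was counted as found in another list when at least 1 bp of it overlapped a peak there. Shares of peaks carry 95% Wilson intervals, which cover counting error only, since neighbouring peaks are not independent. The spread along the genome is given as the SD or range over the 19 autosomes, which are not replicates either. The overlap expected by position alone came from 100 circular shifts of a list along its chromosomes. Widths were compared for peaks that overlap exactly 1 peak of the other list. Regions were formed by merging all 6 lists, and odds ratios over regions carry Woolf intervals (z = 1.96) for counting error only. Peaks were called over H3K4me3 when they overlapped an H3K4me3 peak of either treatment. Where the score was held, the list was cut into 20 bins of equal size by score, bins with fewer than 20 peaks on either side were left out, and bin differences were weighted by the peaks on both sides. Its SE is a jackknife over the 19 autosomes. The number of bins and the weights were changed from a first version with 10 bins, after simulated H3K4me2 lists without a gap had given one and after shares by score had been seen in the real lists. The interval functions gave the same counts as bedtools 2.31.1 on simulated lists. On the vehicle lists of both marks with simulated overlap that depended on score alone, the score-held gap came out at −0.379 percentage points for 40432 H3K4me1 peaks and −0.208 for 21447 H3K4me2 peaks. With a simulated gap of −10 points it came out at −10.6 and −8.54. The simulated overlap rose in a straight line with the rank of the score. That of the real vehicle H3K4me2 list rose more steeply among low scores, so the simulation can understate the error for this mark. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

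The comparisons, the alternatives and the rule for the regions named in the text were fixed before the data were examined, except where stated. Without a gene annotation of the build, the rule names, per list, the 5 widest peaks and the 5 highest-scoring peaks found in that treatment only, and the 5 widest regions with a peak in 1 treatment only for all 3 marks. Alternatives were another overlap rule, a stricter score threshold (the median score of both lists of a mark pooled, which for H3K4me3 is 3100), lists cut to equal length by score, merging of peaks within 1 kb, and autosomes only. The comparison of peaks over and outside H3K4me3, the coverage around H3K4me3 peaks and the values by chromosome and by 1 Mb window were added after the data had been seen.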

Results

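Genome-wide peak lists of H3K4me1, H3K4me2 and H3K4me3 were compared between C2C12 cells differentiated for 48 h with the LSD1 inhibitor S2101 (10 µM) or with vehicle. LSD1 (Kdm1a) removes methyl groups from mono- and dimethylated H3K4 but not from trimethylated H3K4, so the design asks how the distribution of the 3 methylation states differs when the enzyme is inhibited. H3K4me3 is the mark of active promoters, H3K4me1 is typical of enhancers and of the flanks of promoters, and H3K4me2 occurs at both. There was 1 library per mark and treatment, and the lists hold between 13589 and 40432 peaks. The number of reads behind them is unknown. No difference between treatments below has a replicate check.

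The S2101 lists covered less of the genome than the vehicle lists for H3K4me1 and H3K4me2 and slightly more for H3K4me3. H3K4me1 peaks numbered 40432 with vehicle and 20664 with S2101, and covered 26.9 Mb and 9.34 Mb, a ratio of 0.347 (S2101 over vehicle; 0.335 ± 0.037, SD over 19 autosomes). H3K4me2 peaks covered 34.1 Mb with vehicle and 15.9 Mb with S2101, a ratio of 0.467 (0.468 ± 0.033, SD over 19 autosomes), although the S2101 list held more peaks, 24444 against 21447. H3K4me3 peaks numbered 13589 with vehicle and 14324 with S2101, and covered 24.4 Mb and 26.8 Mb, a ratio of 1.10 (1.10 ± 0.0059, SD over 19 autosomes). The direction of the covered length was the same on all 19 autosomes for each mark. The median width was 535 bp with vehicle and 384 bp with S2101 for H3K4me1, 1342 bp and 552 bp for H3K4me2, and 1668 bp and 1737 bp for H3K4me3. The scores quoted here and below are the authors' and rank peaks within a list only. In the H3K4me3 lists, 56.5% of vehicle and 59.8% of S2101 peaks had a score of 3100 or more, most of them exactly 3100 (7504 and 8431 peaks), so scores do not rank these. The number of peaks and their widths depend on the reads in each library, so these totals describe the lists and not the amount of each mark per cell.

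**Figure D1:**
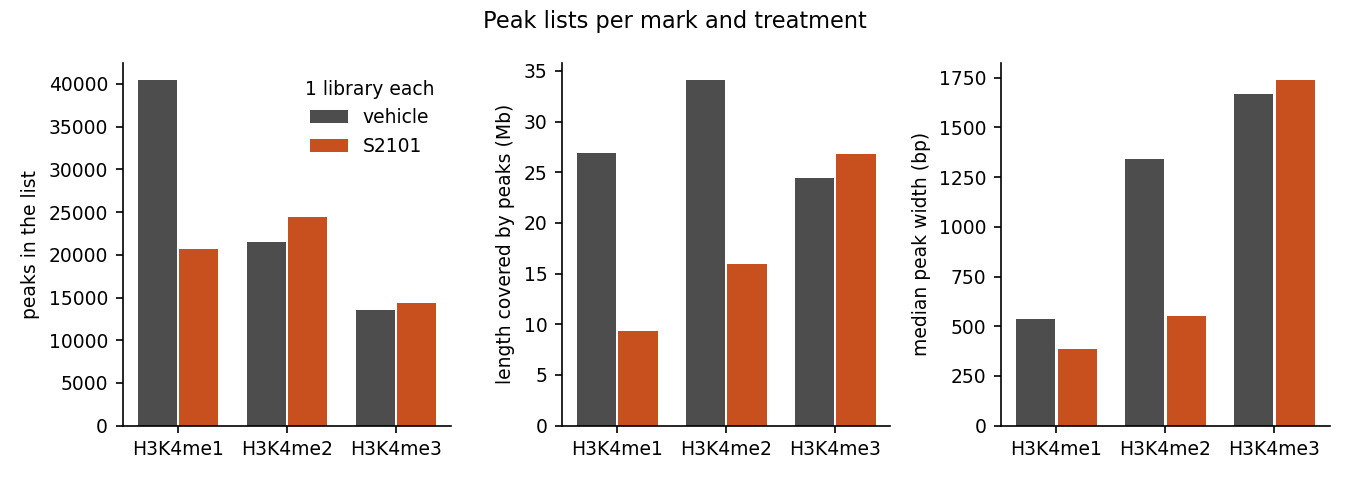
Number of peaks, length covered (Mb) and median peak width (bp) for each mark, with 1 library per bar and no error bars; grey bars are vehicle and orange bars S2101. H3K4me1 has 40432 and 20664 peaks, H3K4me2 covers 34.1 and 15.9 Mb, and H3K4me3 differs least, with 24.4 and 26.8 Mb.

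At an overlap of at least 1 bp, the H3K4me1 lists overlapped least between treatments. Of the 40432 vehicle peaks, 33.0% overlapped an S2101 peak (95% Wilson interval 32.5 to 33.4%; range over autosomes 21.7 to 44.9%), against 1.0% expected from shifted lists. In the other direction, 72.5% of the 20664 S2101 peaks overlapped a vehicle peak (71.9 to 73.1%), against 1.99% expected. Peaks found in vehicle only, 27103 in number, had a median score of 156 and a median width of 481 bp, compared with 296 and 761 bp for vehicle peaks with an S2101 counterpart. The share found again was 83.8% (82.6 to 84.9%) in the highest-scoring 10% of the vehicle list and 11.9% (10.9 to 12.9%) in the lowest-scoring 10%. The 5676 peaks found in S2101 only had a median score of 119 and a median width of 313 bp. Among the 10293 peaks that overlapped exactly 1 peak of the other list, the S2101 peak was 0.606 times as wide at the median (quartiles 0.438 and 0.821), and it was narrower in 87.5%. With a reciprocal overlap of at least 50%, the shares were 15.5% of vehicle and 30.4% of S2101 peaks, and the lowest share among the S2101 lists was then that of H3K4me2, 23.4%.

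The widest vehicle H3K4me1 peak lay on chromosome 15 (77626432 to 77638794, 12363 bp, score 3100). S2101 peaks covered 10425 bp of it, including a peak at 77631080 to 77634353, and no H3K4me3 peak of either treatment lay there. The next widest, on chromosome 10 (80870465 to 80879689, 9225 bp), was covered over 7971 bp with S2101 and also lacked H3K4me3. A peak of 8210 bp on chromosome 11 (117172659 to 117180868) had 6718 bp covered with S2101, and one of 7085 bp on chromosome 15 (58891251 to 58898335) had 4125 bp. Covered lengths were counted within the bounds of the named peak. The vehicle peak that is the third by width, on chromosome 11 (3040439 to 3048917, 8479 bp, score 166.02), overlapped the widest S2101 H3K4me1 peak, of 9431 bp. The highest-scoring H3K4me1 peak without any S2101 counterpart was on chromosome 1 (157082723 to 157086001, 3279 bp, score 1514.61), with no H3K4me2 or H3K4me3 peak in either treatment. Others were on chromosome 17 (25891447 to 25894062, score 1453.54, and 56469782 to 56471700, score 1356.53), on chromosome 5 (34869523 to 34872087, score 1289.89) and on chromosome 12 (17734166 to 17736104, score 1231.42). The one on chromosome 5 lay within H3K4me2 over its full 2565 bp in vehicle, and H3K4me3 covered 966 bp of it with vehicle and 991 bp with S2101. In the opposite direction, the highest-scoring S2101-only peaks were on chromosome 2 (167098402 to 167099677, score 549.26), chromosome 3 (103461025 to 103461996, score 505.31) and chromosome 12 (88175772 to 88176827, score 465.95), each without another mark in either treatment.

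**Figure D2:**
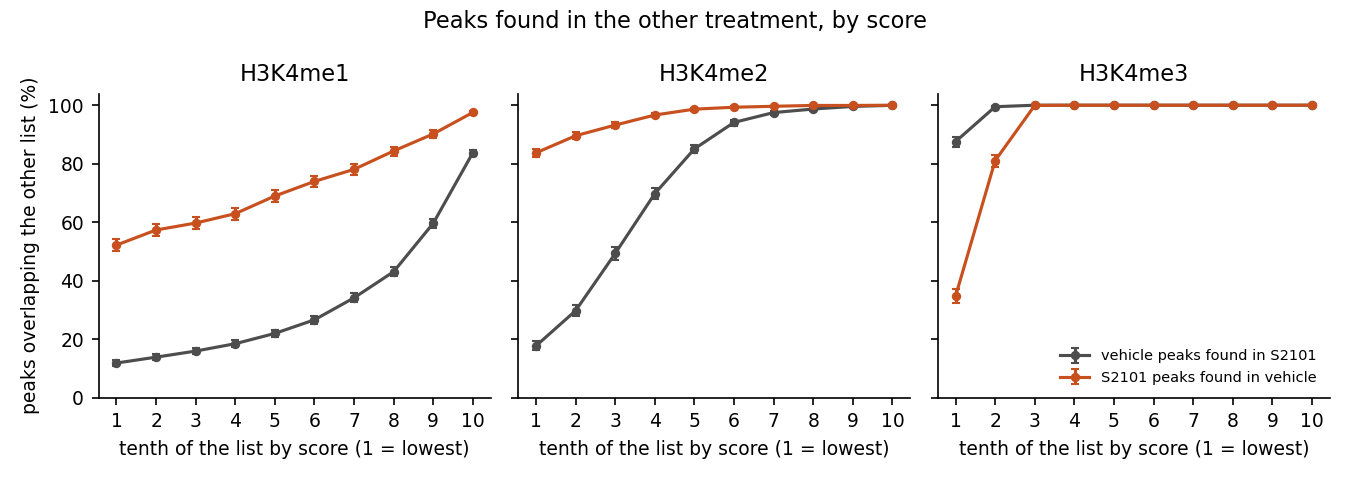
Percentage of peaks that overlap a peak of the other treatment (y axis) in steps of 10% of the list ordered by the authors' score (x axis, 1 is lowest), for each mark; grey, vehicle peaks found in S2101; orange, S2101 peaks found in vehicle; error bars are 95% Wilson intervals for counting error only. Vehicle H3K4me1 peaks go from 11.9% to 83.8%, and vehicle H3K4me3 peaks from 87.6% to 100%.

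H3K4me2 peaks with S2101 lay almost entirely inside the vehicle peaks but were narrower. Of the 24444 S2101 peaks, 96.1% overlapped a vehicle peak (95% Wilson interval 95.8 to 96.3%), whereas 74.2% of the 21447 vehicle peaks overlapped an S2101 peak (73.6 to 74.7%); shifted lists gave 1.91% and 1.80%. In bases, 97.3% of the S2101 length fell within vehicle peaks and 45.5% of the vehicle length within S2101 peaks. A vehicle peak was split over 2 S2101 peaks in 4332 cases and over 3 or more in 1338. For the 10188 peaks with a single counterpart the S2101 peak was 0.503 times as wide at the median (quartiles 0.372 and 0.633), and it was narrower in 99.6%. The 5542 vehicle-only peaks had a median score of 168, compared with 671 for those with a counterpart, and the 964 S2101-only peaks had a median score of 125 in their own list. The overlap depends on the rule: with a reciprocal overlap of at least 50%, 26.7% of vehicle and 23.4% of S2101 peaks were shared.

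The broadest vehicle H3K4me2 domains were largely covered with S2101 too, but by several separate peaks, as the widest S2101 H3K4me2 peak was 5849 bp. The widest vehicle peak, on chromosome 15 (102783239 to 102805133, 21895 bp), had 16300 bp covered with S2101, and its H3K4me3 coverage was 16125 bp with vehicle and 17249 bp with S2101. The domains on chromosome 15 at 85502193 to 85520071 (17879 bp) and at 76022738 to 76039380 (16643 bp) had 13644 bp and 12805 bp covered with S2101, and the one on chromosome 6 (52169147 to 52185482, 16336 bp) had 14141 bp. The highest-scoring vehicle-only H3K4me2 peak was on chromosome 1 (194676835 to 194681631, 4797 bp, score 1557.1). It lay over H3K4me3 peaks that covered 1988 bp with vehicle and 2083 bp with S2101. A peak on chromosome 4 (80556765 to 80560437, score 1310.65) likewise had no H3K4me2 with S2101 while H3K4me3 covered 2686 bp with vehicle and 3077 bp with S2101. On chromosome 2 (84476133 to 84479839, score 1183.76) the vehicle-only H3K4me2 peak had no H3K4me3, and H3K4me1 covered 3466 bp with vehicle and 902 bp with S2101. The S2101-only H3K4me2 peaks with the highest scores were on chromosome 1 (172994624 to 172994836, 213 bp, score 527.83), chromosome 15 (97494213 to 97494868, 656 bp, score 521.17) and chromosome 10 (96078759 to 96079386, 628 bp, score 409.49). All 5 peaks of this kind overlapped an S2101 H3K4me3 peak, and 2 of them a vehicle H3K4me3 peak.

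H3K4me3 was listed at nearly the same places in both treatments, with slightly wider peaks under S2101. Of the 13589 vehicle peaks, 98.7% overlapped an S2101 peak (95% Wilson interval 98.5 to 98.9%), and of the 14324 S2101 peaks, 91.6% overlapped a vehicle peak (91.1 to 92.0%); shifted lists gave 2.07% and 1.96%. The S2101 peak was 1.06 times as wide at the median for the 12212 peaks with a single counterpart (quartiles 1.0 and 1.14; range over autosomes 1.05 to 1.06) and was wider in 74.7%. The 176 vehicle-only and the 1207 S2101-only peaks had median scores of 121 and 151 in their lists. The widest vehicle peak, on chromosome 1 (148339931 to 148349996, 10066 bp), was covered in full with S2101, as were those on chromosome 1 (82279211 to 82289041, 9831 bp) and on chromosome 4 (88579214 to 88588461, 9248 bp). The widest S2101 peak, on chromosome 15 (76024296 to 76038563, 14268 bp), had 13082 bp covered with vehicle.

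H3K4me3 regions listed in 1 treatment only, S2101 or vehicle, mostly held vehicle H3K4me2, but less often than those listed in both. After merging, 1072 regions had H3K4me3 with S2101 only, and 73.8% of them (95% Wilson interval 71.1 to 76.3%) held a vehicle H3K4me2 peak and 41.8% (38.9 to 44.8%) a vehicle H3K4me1 peak. Of the 147 regions with H3K4me3 in vehicle only, 70.7% (62.9 to 77.5%) held a vehicle H3K4me2 peak and 38.1% a vehicle H3K4me1 peak. Among the 12715 regions with H3K4me3 in both treatments these shares were 97.1% and 38.9%. The highest-scoring S2101-only peaks were on chromosome 17 (39979877 to 39985843, 5967 bp, score 1064.77), chromosome 2 (25147476 to 25148491, score 581.33), chromosome 16 (4641838 to 4643591, score 577.91), chromosome 3 (125640724 to 125642107, score 575.49) and chromosome 10 (80748027 to 80749296, score 556.37). All 5 overlapped H3K4me2 peaks of both treatments. Among vehicle-only H3K4me3 peaks the highest score was 264.65, on chromosome 11 (77317055 to 77317904), where vehicle H3K4me2 covered 845 of the 850 bp and S2101 H3K4me2 none. H3K4me3 comes from another experiment than the other marks, so the mark and the experiment cannot be told apart in these contrasts.

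Within each treatment, H3K4me2 followed H3K4me3 closely while H3K4me1 lay mainly elsewhere. Of the vehicle H3K4me2 peaks, 71.8% overlapped H3K4me3 (95% Wilson interval 71.2 to 72.4%), and of the S2101 H3K4me2 peaks 89.5% (89.1 to 89.9%). In the reverse direction, 96.6% of vehicle and 88.2% of S2101 H3K4me3 peaks overlapped H3K4me2. H3K4me1 peaks overlapped H3K4me3 in 13.8% of cases with vehicle and 8.68% with S2101, and overlapped H3K4me2 in 30.4% and 10.4%. Conversely, H3K4me2 peaks overlapped H3K4me1 in 43.5% of cases with vehicle (range over autosomes 22.6 to 73.4%) and in 8.51% with S2101. H3K4me3 peaks with an H3K4me1 peak made up 33.8% of the vehicle list (33.0 to 34.6%) and 11.3% of the S2101 list (10.7 to 11.8%). These shares depend on the lists and the rule: they were 17.3% and 11.1% with lists of equal length, 6.0% and 0.880% with at least 50% of the H3K4me3 peak covered, and 19.1% and 3.19% with the stricter score threshold. At that threshold, H3K4me1 peaks overlapped H3K4me3 in 7.41% (vehicle) and 3.73% (S2101) of cases and H3K4me2 in 19.9% and 4.56%. Shifted lists gave between 0.928% and 3.17% for these overlaps. The shares with H3K4me1 varied widely between chromosomes, from 14.3 to 66.7% of H3K4me3 peaks with vehicle and from 4.15 to 31.4% with S2101.

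Around the 13413 vehicle H3K4me3 peaks that had an S2101 counterpart, H3K4me1 formed shoulders on both sides. With vehicle, 10.3% of positions 1 kb to either side were covered by an H3K4me1 peak, 5.79% of the midpoints, and 3.51% of positions at +10 kb. With S2101 the shoulders were at 2.47% and 2.59%, the midpoint at 0.969%, and +10 kb at 1.17%. H3K4me2 covered 91.8% of the midpoints with vehicle and 59.6% with S2101, and 53.7% and 22.7% of the positions at −1 kb. H3K4me3 covered 39.1% of the positions at −1 kb with vehicle and 44.8% with S2101.

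**Figure D3:**
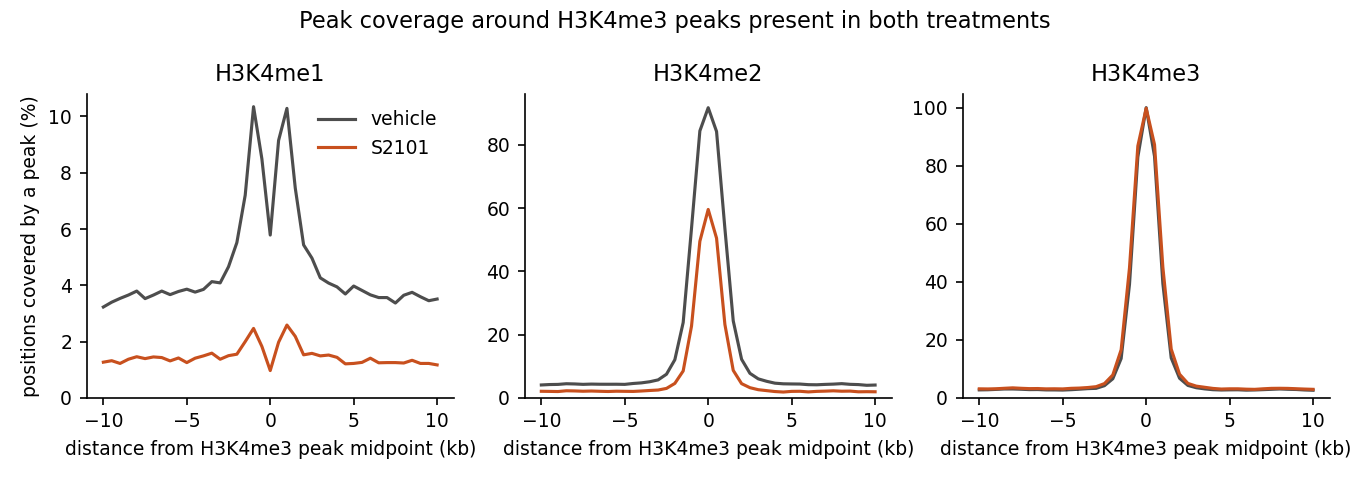
Percentage of positions covered by a peak (y axis, a separate scale in each panel) at distances of up to 10 kb from the midpoint of 13413 vehicle H3K4me3 peaks that overlap an S2101 peak; grey, vehicle; orange, S2101, with 1 library per line. H3K4me1 coverage at −1 kb is 10.3% in vehicle and 2.47% in S2101, and the vehicle H3K4me3 line is at 100% at the midpoint because of how the positions were chosen.

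H3K4me1 and H3K4me2 peaks differed in where the vehicle peaks without an S2101 counterpart lay, in a comparison added after the data had been seen. Vehicle H3K4me1 peaks over H3K4me3 were found again with S2101 in 22.9% of 6556 cases (95% Wilson interval 21.9 to 24.0%), and those outside H3K4me3 in 34.9% of 33876 (34.4 to 35.4%). Their median scores were close, 175 and 184. With the score held, the share over H3K4me3 was lower by 9.59 percentage points on the weighted average (gap −9.59, jackknife SE 0.59), in all 20 score bins. Vehicle H3K4me2 peaks over H3K4me3 were found again in 89.1% of 16280 cases (88.6 to 89.6%), and those outside in 27.0% of 5167 (25.8 to 28.3%). Their scores differed, with medians of 658 and 169. With the score held, a gap of 29.8 percentage points remained (jackknife SE 0.98), over the 14 score bins that could be compared. Peak width was not held, and its medians were 1569 bp over and 859 bp outside H3K4me3. With at least 50% of the peak covered, the shares over and outside H3K4me3 were 12.1% and 19.97% for H3K4me1, and 54.0% and 8.05% for H3K4me2. From S2101 to vehicle, the gap at the 1 bp rule was 0.523 points for H3K4me1 (SE 1.43) and 20.5 points for H3K4me2 (SE 0.996). Counted within 1 kb, the H3K4me1 gap was −17.3 points (SE 0.722) from vehicle to S2101 and −5.88 (SE 1.48) from S2101 to vehicle. For H3K4me2 these were 38.1 (SE 1.19) and 18.5 (SE 0.958).

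Regions with a mark in 1 treatment only were crossed between marks over all merged regions. These leave out every place without a peak, and most hold no H3K4me2 or H3K4me3. By itself this pushes odds ratios with H3K4me1 below 1 and those of H3K4me2 and H3K4me3 above 1. No direction is therefore read from the ratios over all regions. Of 51372 merged regions, 24140 had H3K4me1 with vehicle only and 4613 had H3K4me2 with vehicle only, and 1174 had both, against 2168 under independence (odds ratio 0.354, 95% interval 0.330 to 0.379). The largest class, 18882 regions, held H3K4me1 with vehicle only and no other mark. For S2101-only peaks of H3K4me1 and H3K4me2, 23 regions were seen against 72.5 (odds ratio 0.291, 0.192 to 0.442). In the 9644 regions that held both marks in some treatment, a restriction chosen after the data had been seen, the ratios were 0.511 (0.467 to 0.558) for vehicle only and 1.71 (1.11 to 2.65) for S2101 only. Over all regions, H3K4me2 and H3K4me3 coincided in 38 against 13.2 under independence for vehicle only (odds ratio 3.55, 2.45 to 5.15). For S2101 only it was 63 against 14.7 (4.83, 3.70 to 6.30). In the regions with both marks these ratios were 6.94 and 19.4, so there they coincided more often than under independence. For H3K4me1 and H3K4me3 the odds ratios were 0.288 (vehicle only, 30 regions) and 0.221 (S2101 only, 27 regions), and 0.603 (0.360 to 1.01) and 0.928 (0.620 to 1.39) in the regions with both marks. With the stricter score threshold, over all regions, the ratio for H3K4me1 and H3K4me2 was 0.148 for vehicle only, those for H3K4me1 and H3K4me3 were 0.151 for vehicle only and 0.149 for S2101 only, and that for H3K4me2 and H3K4me3 was 1.40 for S2101 only. Regions with all 3 marks in 1 treatment only were few. There were 10 for vehicle, the widest on chromosome 11 (23418772 to 23420745, 1974 bp), chromosome 12 (103089535 to 103091307), chromosome 18 (62209184 to 62210896), chromosome 6 (135317154 to 135318738) and again chromosome 11 (45696680 to 45697961). There was 1 for S2101, on chromosome 5 (141225226 to 141225750, 525 bp). H3K4me1 and H3K4me2 of a treatment come from the same experiment, so their lists can be linked by the culture or the input.

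The number of H3K4me1 peaks relative to H3K4me3 peaks differed between chromosomes in both treatments. It was highest on chromosome 15, with 5.31 per H3K4me3 peak for vehicle and 3.13 for S2101, and lowest among the autosomes on chromosome 7, with 1.72 and 0.688. On the X chromosome it was 0.178 and 0.0464, from 77 and 21 H3K4me1 peaks. The S2101 list held fewer H3K4me1 peaks on every chromosome shown, with ratios of S2101 over vehicle from 0.414 on chromosome 7 to 0.647 on chromosome 15 among the autosomes. This comparison was added after the data had been seen.

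**Figure D4:**
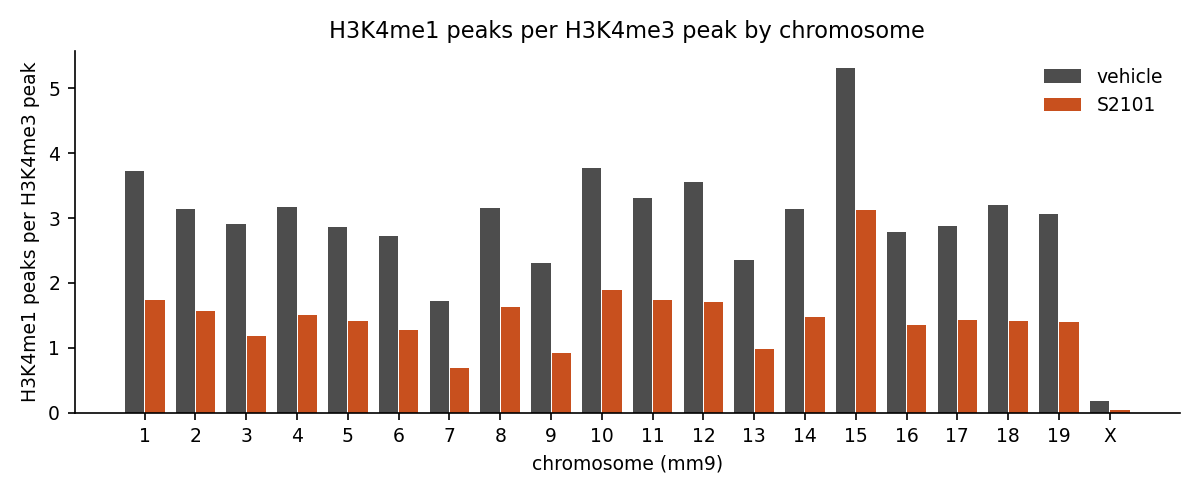
H3K4me1 peaks per H3K4me3 peak (y axis) on each of the 19 autosomes and X (x axis), with 1 library per mark and treatment and no error bars; grey, vehicle; orange, S2101. Chromosome 15 stands highest, with 5.31 and 3.13, and X lowest, with 0.178 and 0.0464.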

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

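The covered length was a planned comparison, while the tests of the 3 patterns that follow it were chosen after the peak lists had been seen. The tests of overlap within 1 kb, of H3K4me3 widening and of chromosome copy number had their predictions written before their own results were known. The covered length stood out because the marks went in opposite directions: the ratio of S2101 over vehicle was 0.347 for H3K4me1, 0.467 for H3K4me2 and 1.10 for H3K4me3. The difference between marks was not tested, since each rests on 1 library per treatment, and H3K4me3 comes from another experiment.

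H3K4me1 peaks over H3K4me3 had an S2101 counterpart less often than those outside. A lower score of these peaks does not account for it, because with the score held the gap was −9.59 percentage points (jackknife SE 0.59), while from S2101 to vehicle it was 0.523 (SE 1.43). Narrow S2101 peaks that just miss the vehicle peak predicted that the gap would close when counted within 1 kb, but it was then −17.3 points (SE 0.722). That rule also counts separate neighbouring peaks, as 34.7% of the gaps between vehicle and 28.5% of those between S2101 H3K4me1 peaks were under 1 kb. The shares rose from 22.9 to 33.0% over and from 34.9 to 52.3% outside H3K4me3, so near misses are not excluded as a part of it. Counted this way, a gap of −5.88 (SE 1.48) appeared from S2101 to vehicle too. A biological candidate, H3K4me3 spreading over its flanks, predicted fewer counterparts where H3K4me3 had widened most. With the score held, the share with a counterpart was 1.23 points higher there (SE 1.38), so the predicted drop was not seen. Without the score held, the shares were 24.2% and 18.4% of 1680 peaks each, at median H3K4me3 width ratios of 1.19 and 0.979. Only H3K4me1 peaks that overlapped a vehicle H3K4me3 peak entered. Those lying wholly in the flanks were not covered, so spreading is not decided. An effect of LSD1 inhibition and a property of this pair of libraries, such as their enrichment at promoters, both stay open, as there is 1 library per treatment.

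H3K4me2 peaks outside H3K4me3 had an S2101 counterpart less often than those over it. The test first chosen for the score as the only cause compared composition, and its result was close to what that explanation predicts: 91.2% of the peaks with a counterpart and 90.5% of as many highest-scoring peaks lay over H3K4me3 (difference 0.742 points, jackknife SE 0.194). That test was replaced after its result had been seen by the one used for H3K4me1, whose prediction here was also written with its result known. With the score held a gap of 29.8 percentage points remained (jackknife SE 0.979), which the score alone would not leave. Peak width was not held, with medians of 1569 bp over and 859 bp outside H3K4me3, and wider peaks overlap more easily. A loss from vehicle to S2101 alone predicted little gap from S2101 to vehicle, a prediction written with the result known. That gap was 20.5 points (SE 0.996). Width was not held there either, with S2101 medians of 584 bp over and 357 bp outside H3K4me3, so this does not decide whether the loss went one way. Peaks outside H3K4me3 thus had fewer counterparts than those over it in both directions, but to unequal degrees. Outside it, 27.0% of 5167 vehicle peaks and 74.7% of 2434 S2101 peaks had a counterpart, so a one-way loss is not excluded, in part or in whole. Over it, these shares were 89.1% and 98.4%. An effect of the inhibitor and one of the libraries, such as local background or enrichment at promoters, stay open and were not tested.

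Chromosomes differed in H3K4me1 peaks per H3K4me3 peak, with 5.31 on chromosome 15 for vehicle, 1.72 on chromosome 7, a median of 3.13 over the autosomes and 0.178 on X. It is not a feature of the S2101 libraries alone, since these vehicle values differ as well. The order over 19 autosomes was alike in both treatments (Spearman rho 0.916, two-sided permutation p 2e-05, the smallest that the permutations can give, adjusted 6e-05 over 3 relations, and Pearson r 0.978, with the same p and adjusted p, and 0.935 without chromosomes 15 and 7). However, 98.7% of vehicle H3K4me3 peaks and 72.5% of S2101 H3K4me1 peaks overlapped a peak of the other treatment. The 2 orders are therefore not independent, the prediction was written with the result known, and the p-values add no support. Chromosome copy number could give this pattern, and would raise H3K4me3 scores on the same chromosomes. The vehicle H3K4me1 median score and the share of vehicle H3K4me3 peaks with a score of 3100 or more had a rho of 0.411 (permutation p 0.0833, adjusted 0.0833, and Pearson r 0.574, p 0.00376, adjusted 0.00376, and 0.435 without chromosomes 15 and 7). On chromosome 15 that share was 61.1% for vehicle and 58.5% for S2101, against autosome medians of 59.0% and 62.0%. This does not decide on copy number, as many H3K4me3 scores stand at 3100 and the H3K4me1 score was used in place of the peaks per H3K4me3 peak. The vehicle median scores of H3K4me1 and H3K4me2 had a rho of 0.674 (permutation p 0.00176, adjusted 0.00264; Pearson r 0.790, p 0.0002, adjusted 0.0003, and 0.566 without chromosomes 15 and 7), but both marks come from 1 experiment, so this does not decide it either. Chromosomes are not independent replicates, and no biological explanation was tested.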

How the results depend on the processing

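The alternatives were chosen before the data were examined, except the restriction to regions with both marks and the alternatives for peaks over and outside H3K4me3, which were chosen after seeing the data. No paired analysis was possible because each mark and treatment has 1 library. The planned counts of gene promoters and gene lists, with their promoter windows, were not run, as the gene table is of another build. No ratio of covered length or width crossed 1 under the alternatives tried for it. Of the values of the main comparisons under these alternatives, 25 lay within the interval or spread of the value reported, 85 moved beyond it and 1 reversed. Only the ratios of length and width and the odds ratios could reverse, by crossing 1. Shares of peaks, which make up most of these values, could not. Shares below are given for vehicle peaks found in S2101 and S2101 peaks found in vehicle, in that order. The depth of the libraries, which is unknown, limits what the lists can show of weak peaks.

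With at least 50% of the peak covered, the shares were 18.7% and 66.7% for H3K4me1, 43.0% and 95.4% for H3K4me2, and 98.5% and 90.7% for H3K4me3. Under that rule vehicle H3K4me1 peaks lay over H3K4me2 in 24.5% and over H3K4me3 in 9.83%, H3K4me2 over H3K4me3 in 68.4%, and H3K4me3 over H3K4me1 in 6.0% and over H3K4me2 in 95.4%; for S2101 these were 6.71%, 6.39%, 88.3%, 0.880% and 60.9%. With a reciprocal overlap of at least 50%, the shares were 15.5% and 30.4%, 26.7% and 23.4%, and 93.8% and 89.0% for the 3 marks, and the width ratios 0.752 for H3K4me1 and 0.631 for H3K4me2. This rule drops pairs whose widths differ most, which by itself moves the width ratios towards 1. The same number of peaks is then shared from either side, so the order of the 2 shares of a mark follows from the list lengths. Among the S2101 lists the lowest share was then that of H3K4me2, not of H3K4me1. Within 1 kb, the shares were 49.1% and 85.0%, 78.4% and 97.6%, and 99.0% and 92.9%.

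The stricter score threshold sets 1 score for both lists of a mark, so its values also depend on how the score scales with the reads of each library, and for H3K4me3 it keeps only peaks with a score of 3100 or more. With it, the shares were 25.3% and 79.6%, 58.3% and 97.4%, and 99.6% and 89.2%. The covered ratios were 0.255, 0.340 and 1.15, and the width ratios 0.636 for H3K4me1 and 1.05 for H3K4me3. The overlaps of marks, in the order above, were 19.9%, 7.41%, 65.2%, 19.1% and 97.3% for vehicle and 4.56%, 3.73%, 77.8%, 3.19% and 66.9% for S2101. The odds ratios were 0.148 (H3K4me1 and H3K4me2, vehicle only), 0.151 and 0.149 (H3K4me1 and H3K4me3, vehicle only and S2101 only) and 1.40 (H3K4me2 and H3K4me3, S2101 only). With equal list lengths, the shares were 48.9% and 58.5%, 69.5% and 97.7%, and 97.7% and 95.2%, and the covered ratios 0.503 for H3K4me1 and 1.08 for H3K4me3. Vehicle H3K4me1 then lay over H3K4me2 in 35.0% and over H3K4me3 in 12.7%, and vehicle H3K4me3 over H3K4me1 in 17.3%. For S2101, H3K4me1 lay over H3K4me2 in 8.95% and over H3K4me3 in 8.19%, H3K4me2 over H3K4me3 in 91.0%, and H3K4me3 over H3K4me2 in 87.5%. The odds ratio of H3K4me1 and H3K4me2, vehicle only, was 0.508.

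With peaks within 1 kb merged, the shares were 35.6% and 71.1% for H3K4me1 and 75.9% and 95.4% for H3K4me2, and 92.6% of S2101 H3K4me3 peaks were found in vehicle. The covered ratio of H3K4me2 was 0.537, and the width ratios were 0.531 for H3K4me1 and 0.641 for H3K4me2. On autosomes alone, 75.1% of vehicle H3K4me2 peaks were found in S2101. In regions with both marks, the odds ratio of H3K4me1 and H3K4me2 was 0.511 for vehicle only and, reversed, 1.71 for S2101 only. Regions with H3K4me1 alone, which push this ratio below 1 over all regions, are left out there, and no other cause was tested. The others were 0.603 and 0.928 for H3K4me1 and H3K4me3, both with an interval that includes 1, and 6.94 and 19.4 for H3K4me2 and H3K4me3. Vehicle peaks over H3K4me3 were found again less often than those outside for H3K4me1, and more often for H3K4me2, also with at least 50% covered (12.1% and 19.97%; 54.0% and 8.05%), within 1 kb (33.0% and 52.3%; 93.0% and 32.5%) and without chromosomes 15 and X (21.7% and 33.9%; 90.3% and 26.8%).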

Other observations

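The X chromosome differed from the autosomes in its count of H3K4me2 peaks. It held 487 H3K4me2 peaks with vehicle and 229 with S2101, a ratio of 0.470, while all 19 autosomes had more H3K4me2 peaks with S2101 (ratios 1.02 to 1.23). Counts rise where a vehicle peak is split: in the whole list 4332 were split over 2 S2101 peaks and 1338 over 3 or more. The length covered by H3K4me2 was lower with S2101 on all 19 autosomes. More peaks there thus do not mean more H3K4me2, and whether splitting differed on X was not examined. H3K4me1 peaks on X numbered 77 and 21, a ratio of 0.273 against 0.414 to 0.647 on the autosomes, and H3K4me3 peaks 433 and 453. The median score on X was below that of every autosome for vehicle H3K4me1 (140 against 157 to 220.1), vehicle H3K4me2 (218 against 396 to 621) and S2101 H3K4me2 (156 against 215 to 366), but not for S2101 H3K4me1 (135 against 120.4 to 168). A score of 3100 or more was held by 20.8% of vehicle and 32.7% of S2101 H3K4me3 peaks on X, against 46.4 to 62.4% and 53.2 to 64.3% on the autosomes. On chromosome 15 the ratio was the highest of all autosomes for each mark, 0.647 for H3K4me1, 1.23 for H3K4me2 and 1.10 for H3K4me3.

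Vehicle H3K4me1 peaks clustered in some windows of 1 Mb, which were chosen after their values were seen. Among the 739 windows with at least 20 vehicle peaks, the median share found again with S2101 was 33.3% (quartiles 25.5 and 40.9%). The window with the most peaks, on chromosome 1 from 137000001 to 138000000, held 161 with vehicle and 81 with S2101, and 37.3% of the former were found again (95% Wilson interval 30.2 to 45.0%). The highest share was on chromosome 15 from 83000001 to 84000000, where 67.1% of 73 vehicle peaks were found again (55.7 to 76.8%) and S2101 had 86 peaks. On chromosome 6 from 17000001 to 18000000, 1 of 28 vehicle peaks was found again (3.57%, 0.633 to 17.7%).

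The peak on chromosome 17 from 39979877 to 39985843 was the highest-scoring H3K4me3 peak listed with S2101 only (score 1064.77), and the widest S2101 H3K4me2 peak (5849 bp) lay within it. Vehicle H3K4me2 covered all 5967 bp of it and vehicle H3K4me3 none. The wide H3K4me1 peak on chromosome 11 from 3040439 to 3048917 was listed in both treatments, with no other mark. Its score was 166.02 with vehicle, below the list's median of 182, and that of the S2101 peak there 259.91, above its list's median of 142. Whether this peak or the one on chromosome 17 lies in repeated sequence was not examined, so neither is read as an effect of the treatment.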
